A study of Mus musculus with 47 samples.

How the data were processed

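Bulk RNA sequencing was done on the tibialis anterior muscle of 47 female C57BL/6 mice, with 1 library per animal, at ZT0 and ZT12 in 6 conditions. The 12 groups had 4 libraries each, apart from WT ADX at ZT0 with 3. Sample groups, replicate numbers and ages of 8 to 18 weeks were taken from the labels.

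Per the labels' protocols, 60 bp single-end reads averaging 25 M per sample were made. Per the submitters' processing notes, FastQC 0.11.8, Trim Galore 0.5.0, HISAT2 2.1.0, featureCounts 1.6.2 and edgeR 3.30.0 were used with the GRCm38 mouse build. The deposited table holds 1 value per gene and library for 13500 genes, which the authors gave as FPKM on a log2 scale. Its lowest value, -6.64, equals log2 of 0.01, so the deposited values were read as log2(FPKM + 0.01), and their highest value was 14.7. No counts were available. The authors' own statistics were not available either, and no step beyond those in the notes is stated here as fact. Of the Ensembl IDs, 13441 matched a symbol in the GENCODE M21 annotation and 59 did not. Positions are 1-based on GRCm38. Reads shared between near-identical copies, such as Mt1 and Mt2 or the H2-Q genes, cannot be assigned with certainty, and the strand setting of the counting is not recorded.

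All tests were made in R 4.3.3 with limma 3.58.1. Group means of the 12 groups were fitted to the 47 libraries in 1 model on the deposited log2 values (lmFit, contrasts.fit, eBayes with trend), leaving 35 residual degrees of freedom. Tested genes reached 1 FPKM in at least 3 libraries, which held for 12000 genes. For 23 contrasts, two-sided p-values were adjusted by the Benjamini-Hochberg method within the contrast, and a gene was called at an adjusted p under 0.05. The contrasts were ZT12 against ZT0 within a condition, conditions within a time, means of both times, and differences between such effects. Changes are given as log2 fold changes ± SE and groups as mean FPKM ± SD. Because an offset of 0.01 FPKM is small, changes of genes near or at 0 are large on this scale and shrink on log2(FPKM + 1). A value of exactly 0 FPKM is described as listed at 0, with no fold and no mean against it.

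Before the data were examined, 27 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The 25 lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 575 tests of list and contrast. Members were counted by the test over all genes and by the test adjusted over the list alone. The camera test was repeated with the correlation estimated from the data. Not every list past the list test is described. Named genes were, per contrast, the 6 largest rises and 6 largest falls past the test with a mean of at least 1 FPKM, no overlap between the groups and no predicted-gene symbol. Added to these were up to 4 members with the smallest adjusted p of the clock and glucocorticoid receptor lists, of lists past the list test, and of lists with at least 3 called members, plus Arntl throughout. Some genes that this rule names are not reported here. After the data had been seen, the rule was repeated on genes with no value at 0 in the groups compared. The order of genes in the text took account of whether their call held under the alternatives. Some genes named first still lost it in 1 or more of them. The genes plotted, those given by group mean in every condition and those listed at 0 with the value of each library were also chosen after their values were seen.

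The alternatives were log2(FPKM + 1), no filter on low values, equal medians of the libraries, only the groups compared in the model, age as a covariate, the replicate number as a block, and leaving out each library in turn. The block was fitted with only the groups compared in the model. Leaving out genes with any value at 0 and leaving out 7 libraries that share no exact values with their group were added after the data had been seen. Other splits of the libraries, at most 100 per contrast, were counted for each contrast.

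The model was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale among 12000. It recovered 90% and 96% of them for WT ADX against WT sham at ZT0, 82% and 91% for ZT12 against ZT0 in WT sham, and 76% and 93% for the difference between these time effects in WT ADX and WT sham. In those tests 10, 7 and 8 unchanged genes were called. Of 100 unchanged gene lists, 0 were called by camera. The simulated genes varied independently of each other, with the same spread in all groups and no values set to 0. The simulation therefore could not test how camera behaves on lists of correlated genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.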

Results

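The study asked how adrenal hormones and the brain and muscle clocks together set daily gene expression in mouse skeletal muscle. RNA was sequenced from the tibialis anterior, a fast-fibred muscle of the shin, of 47 female mice killed at ZT0 or ZT12, where ZT counts hours from lights on. Wild-type (WT) mice had sham surgery, adrenalectomy (ADX), ADX followed by adrenaline (ADX+ADR, 0.5 mg/kg) or ADX followed by dexamethasone, a synthetic glucocorticoid (ADX+DEX, 5 mg/kg). Injections were given at ZT12 for 10 days. In the injected conditions ZT0 and ZT12 libraries therefore differ in time since the last dose as well as in time of day. No separate vehicle-injected condition is among them, so effects of injection and of the hormone cannot be told apart. RE-RE mice, in which a blocked Bmal1 (Arntl) gene is restored by Cre recombinase in brain and skeletal muscle, had sham surgery or ADX. Each group held 4 libraries, apart from WT ADX at ZT0 with 3.

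The deposited FPKM values carry no counts. From the step between low values of 68 genes listed at 0 in at least 30 libraries, the depth was recovered as 16.3 to 35.8 M reads per library, with a median of 22.7 M. In these genes a median of 100% of a library's 7 to 23 values came out as whole reads within 0.05 read. As the depth was fitted on these values, each was also left out of the fit in turn, and 97.3% of the 657 were still whole. In 1024 genes listed at 0 in 1 to 9 libraries the share was 7.95% to 13.0%, where chance gives 10%. Exactly 0 FPKM was listed for 10102 values (1.59%) in 1389 genes, and 96 of the 3322 genes with a mean over 10 FPKM had such a value. Of these 96, 21 were listed at 0 in WT sham and WT ADX libraries alone, and 9 in WT ADX+ADR and WT ADX+DEX libraries alone. A 0 was therefore not read as absence of a transcript. Within groups, 40 libraries shared 16 to 80 exact low values and 7, all in WT sham or RE-RE groups, at most 1. Libraries of a group may thus not be independent, and p-values below may be too small.

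Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), the clock activator restored in RE-RE mice, was read first in every group. At ZT0 it stood at 16.8 ± 2.05 FPKM in WT sham and 14.4 ± 0.791 in RE-RE sham (SD, n = 4 each), so the restored gene was expressed in RE-RE muscle. WT ADX+ADR had 17.2 ± 0.84 and WT ADX+DEX 23.4 ± 2.02, against 7.41 ± 1.75 in WT ADX (n = 3) and 9.37 ± 2.01 in RE-RE ADX. At ZT12 the WT sham libraries read 0.673, 0.123, 0.758 and 0 FPKM, and RE-RE sham read 0.327 with 3 libraries listed at 0. ZT12 values were 1.8 ± 0.548 in WT ADX, 6.02 ± 0.28 in WT ADX+ADR, 5.33 ± 0.34 in WT ADX+DEX and 2.37 ± 1.29 in RE-RE ADX. Arntl fell past the test in both sham conditions. Its log2 change was -2.06 ± 0.87 in WT ADX (adjusted p = 0.12), -1.51 ± 0.81 in WT ADX+ADR (adjusted p = 0.234) and -2.13 ± 0.81 in RE-RE ADX (adjusted p = 0.247). The pooled spread of this gene includes the libraries near 0, and on log2(FPKM + 1) these changes, -1.59, -1.37 and -1.68, passed the test. In WT ADX+DEX the change of -2.13 passed at an adjusted p of 0.0441 and no longer did when any 1 of its libraries was left out.

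**Figure D1:**
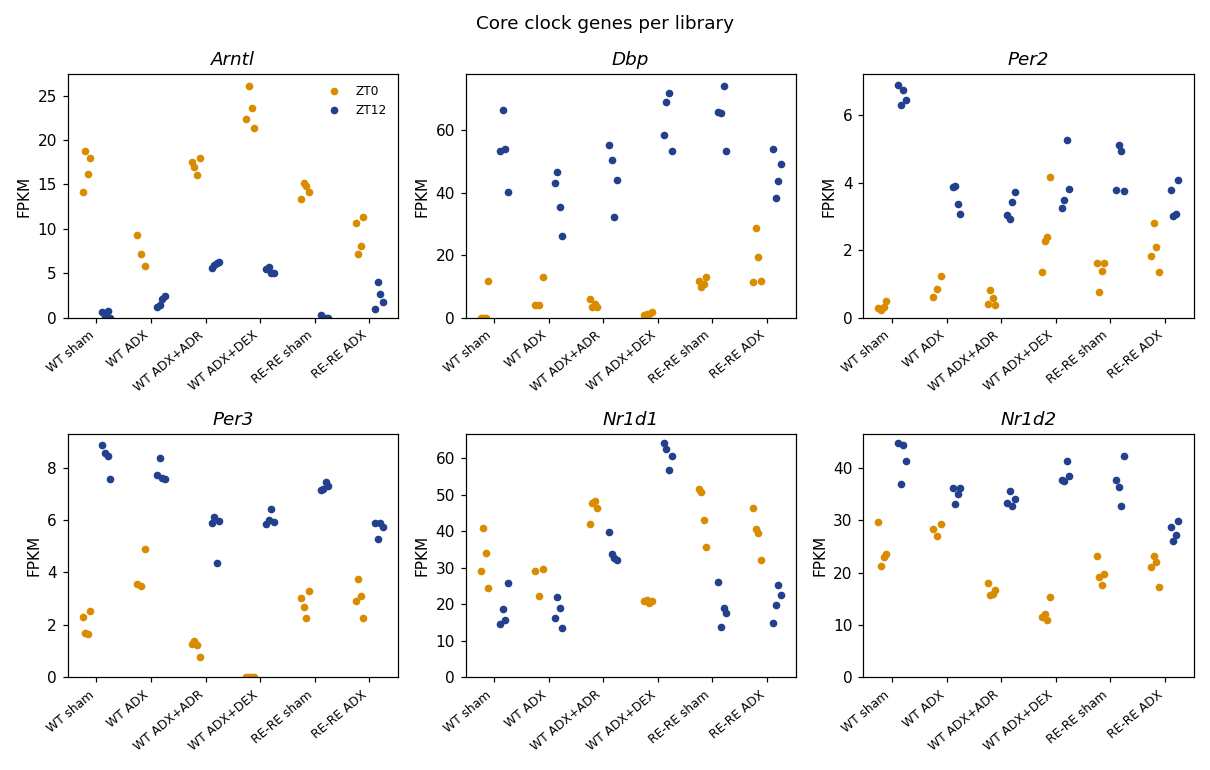
FPKM of 6 clock genes in each library by condition, with ZT0 and ZT12 side by side. Arntl lay at 14.2 to 18.8 FPKM in WT sham at ZT0 and at 0 to 0.758 at ZT12, and Per3 was listed at 0 in all 4 WT ADX+DEX libraries at ZT0.

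ZT12 was first compared with ZT0 in WT sham, to show which muscle genes differ by time of day with adrenals intact. The clock repressors Per3 (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665) and Per2 (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324) rose. Per3 went from 2.06 ± 0.441 to 8.36 ± 0.557 FPKM and Per2 from 0.33 ± 0.114 to 6.59 ± 0.259. The clock-controlled transcription factor Tef rose by 1.21 ± 0.08, while Nr1d1 (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333) fell from 32.1 ± 7.08 to 18.8 ± 5.06. Dbp was listed at 0 in 3 libraries at ZT0 and at 11.9 in the other, against 40.2 to 66.5 at ZT12. In the core clock list 11 of 19 members rose, 6 fell and 2 did not pass, with the same counts adjusted over the list alone. That list stood up (adjusted p = 0.00465, 0.425 with an estimated correlation, and 0.0737 with only WT sham in the model).

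Glucocorticoid receptor targets moved together in WT sham. Glul (ENSMUSG00000026473, chromosome 1, 153899944 to 153909723), glutamine synthetase, rose from 22.6 ± 5 to 111 ± 16.3 FPKM (2.31 ± 0.2, adjusted p = 7.93e-11). The sulfotransferase Sult1a1 (ENSMUSG00000030711, chromosome 7, 126672865 to 126676432) rose from 6.73 ± 0.327 to 17.2 ± 1.95, and Klf15 (ENSMUSG00000030087, chromosome 6, 90462576 to 90475238) from 9.78 ± 2.21 to 20.1 ± 2.79. Klf9 (ENSMUSG00000033863, chromosome 19, 23141226 to 23168134) rose from 38.8 ± 4.58 to 62.1 ± 7.31, and Cebpb by 2.16 ± 0.26. Of 25 targets 19 rose, 1 fell and 5 did not pass, also when adjusted over the list alone, and 12 had a value at 0 (list test adjusted p = 1.02e-14, and 0.0516 with an estimated correlation). Pik3r1, a regulatory subunit of PI3-kinase, was listed at 0 in all 4 ZT0 libraries and at 2.74 to 7.58 FPKM at ZT12. Per1 read 0.344, 0, 0 and 0.978 at ZT0 and 14.4 to 22.9 at ZT12.

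Rhythmic muscle output genes rose too. Tspan4 rose by 1.48 ± 0.1 (adjusted p = 1.82e-14), the deubiquitinase Usp2 by 1.84 ± 0.16, and the sarcomeric titin-cap gene Tcap from 1230 ± 204 to 2690 ± 326 FPKM. Of 14 such genes 6 rose and 1 fell, also adjusted over the list alone (list test adjusted p = 0.000468, and 0.194 with an estimated correlation). The atrophy regulators Foxo1 (1.28 ± 0.17) and Foxo3 (0.63 ± 0.08) and alcohol dehydrogenase Adh1 (2.24 ± 0.23) rose. Rgs2 (-2.4 ± 0.44), the glycolytic regulator Pfkfb3 (-1.48 ± 0.35), the sterol regulator Srebf2 (-0.54 ± 0.08) and the endothelial receptor Kdr (-0.99 ± 0.13) fell. In the cAMP and adrenergic response list 1 of 18 members rose and 11 fell, also adjusted over the list alone (adjusted p = 1.69e-05, and 0.237 with an estimated correlation). With genes listed at 0 left out, which takes 6 members away, its adjusted p was 0.0557. The immediate stress list, fixed as a sign of handling and RNA quality and sharing 5 of its 10 members with the cAMP list, fell as well, in 5 cases with no rise (adjusted p = 0.00468, 0.498 with an estimated correlation, and 0.276 without genes listed at 0). The fall of the cAMP list is therefore not separable from handling. In all, 2818 of 12000 genes were called, 1678 up and 1140 down, and 289 of them changed at least 2-fold. Without the 7 libraries that stood apart 1295 were called. Changes of low genes depended on the offset: Per2 rose by 4.33 ± 0.27 here and by 2.51 on log2(FPKM + 1).

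**Figure D2:**
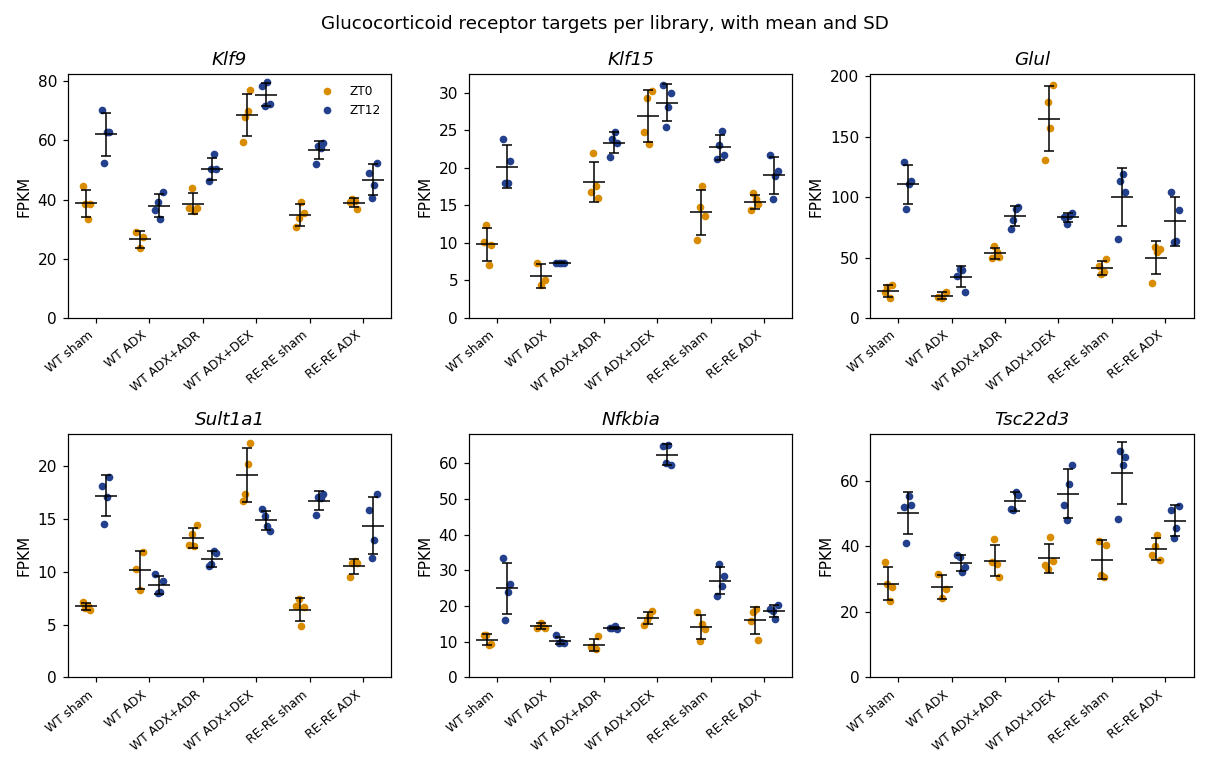
FPKM of 6 glucocorticoid receptor targets in each library by condition and time, with bars for the group mean ± SD. Glul stood at 22.6 and 111 FPKM at ZT0 and ZT12 in WT sham, and at 165 and 83.2 in WT ADX+DEX.

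The same comparison in WT ADX asked what remains of the difference between ZT0 and ZT12 without adrenal hormones. Clock genes still changed. Per3 rose by 0.99 ± 0.16 (adjusted p = 5.8e-05), from 3.98 ± 0.78 to 7.81 ± 0.37 FPKM, Tef by 0.64 ± 0.09, Usp2 by 0.88 ± 0.17, Tcap by 0.99 ± 0.11 and the P450 reductase Por by 0.45 ± 0.09. The centrosomal gene Tacc2 rose by 2.15 ± 0.19. Clock list counts were 8 up, 3 down and 8 not past, or 10 up and 5 down adjusted over the list alone (list test adjusted p = 0.0596). Rhythmic muscle output genes rose in 5 of 14 cases, also adjusted over the list alone, with no fall (adjusted p = 0.000728, and 0.214 with an estimated correlation). Glucocorticoid receptor targets showed no common direction: 5 rose, 3 fell and 17 did not pass, or 8 and 6 adjusted over the list alone. Their list test had an adjusted p of 0.767, with a median change of 0.06, a mean of -0.27 and an upward test direction. Sult1a1 read 10.2 ± 1.8 FPKM at ZT0 and 8.74 ± 0.857 at ZT12 (adjusted p = 0.314). Ddit4, a stress-induced mTORC1 inhibitor and receptor target, read 0.854, 2.93 and 2.6 FPKM at ZT0 and was listed at 0 in all 4 libraries at ZT12.

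Among cell-type lists in WT ADX, macrophage genes were lower at ZT12: 5 of 11 fell, or 6 adjusted over the list alone (adjusted p = 4.22e-05, and 0.374 with an estimated correlation). Fibroblast and matrix genes fell in 3 of 16 cases (adjusted p = 6.5e-05, and 0.531 with an estimated correlation). In all, 1322 genes were called, 917 up and 405 down. The count was 547 without ZT0 replicate 2, 763 without ZT12 replicate 5, and 44 when only these 7 libraries entered the model. Klf9 (0.51 ± 0.1) and Cebpb (1.43 ± 0.28) rose in the model of all libraries and missed the test in that smaller one.

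Whether ADX altered the time-of-day difference was tested directly. Receptor targets had smaller rises from ZT0 to ZT12, which a shift in the time of their peak would also give. The ZT12 change of Sult1a1 was lower in WT ADX than in WT sham by 1.55 on the log2 scale (-1.55 ± 0.17, adjusted p = 1.52e-07). That of Nfkbia, the inhibitor of NF-κB, was also lower (-1.68 ± 0.25, adjusted p = 5.65e-05), as were those of the phosphatase Dusp7 (-1.69 ± 0.33) and Tspan4 (-1.14 ± 0.14). Of 25 targets 11 had a lower time effect after ADX, 1 a higher and 13 did not pass, against 15 lower and 1 higher adjusted over the list alone. With 12 members listed at 0 somewhere, the list test gave an adjusted p of 7.19e-20, and 0.0344 with an estimated correlation. This was 1 of 4 list calls out of 172 that held with an estimated correlation, all of them of this list. The clock genes Per3 (-1.05 ± 0.21), Per2 (-2.31 ± 0.39, or -1.24 on log2(FPKM + 1)) and Tef (-0.56 ± 0.12) also had smaller rises in WT ADX. In the clock list 4 members had a lower and 2 a higher time effect, or 10 and 5 adjusted over the list alone (adjusted p = 0.011, 0.498 with an estimated correlation, and 0.0695 without the genes listed at 0). The cAMP list moved up, with 2 members called, 4 over the list alone (adjusted p = 4.41e-05, and 0.269 with an estimated correlation). The immediate stress list, the sign of handling, moved up with it, with 1 member called (adjusted p = 0.00461, 0.498 with an estimated correlation, and 0.191 without genes listed at 0). Other lists moved with few or no members called: oxidative phosphorylation up (adjusted p = 0.000186, and 0.692 with an estimated correlation), mitochondrially encoded genes up (adjusted p = 0.0106, and 0.0518 with only these groups in the model), macrophage genes down (adjusted p = 0.0214, and 0.0563 without genes listed at 0) and tendon genes down (adjusted p = 0.0307, and 0.161 with only these groups in the model). The difference was called for 185 genes, 80 up and 105 down. The count was 118 without WT sham ZT12 replicate 8, 70 with only these groups in the model and 96 without the 7 libraries that stood apart.

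**Figure D3:**
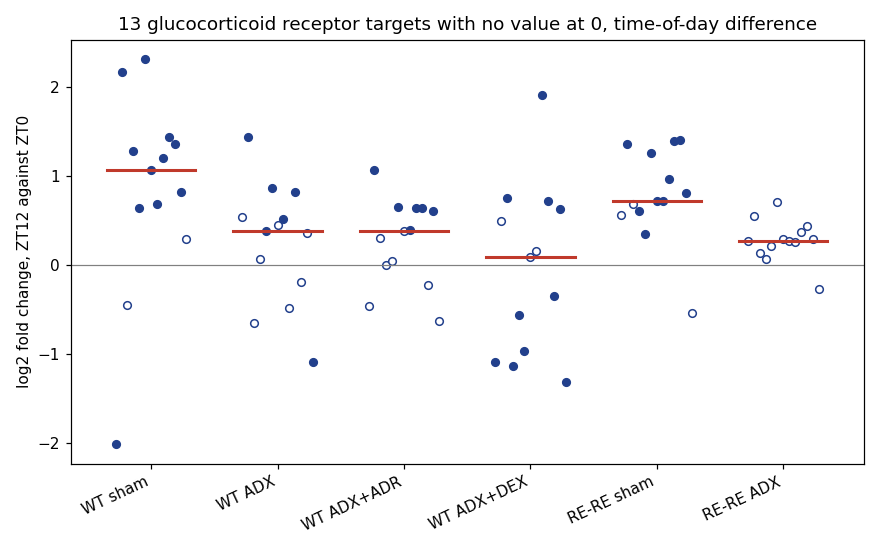
Log2 change from ZT0 to ZT12 of the 13 glucocorticoid receptor targets never listed at 0, by condition, with filled points past the test and a red line at the median. Sult1a1 lay at 1.35 in WT sham, -0.2 in WT ADX, 1.4 in RE-RE sham and 0.43 in RE-RE ADX.

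WT ADX was then compared with WT sham at each time, for the effect of losing the adrenals. Age parted the groups compared: 9 to 11 weeks in WT sham and 12 to 15 in WT ADX at ZT0, and 10 to 12 against 13 to 17 at ZT12. With age as a covariate, whose slope comes from within the 12 groups, 3273 genes were called at ZT0. Nnt, the mitochondrial transhydrogenase, and Wdfy1, a WD repeat gene, chosen after their values were seen, also set WT ADX apart from the other conditions. Nnt was listed at 0 in all 7 WT ADX libraries and in 2 of 8 WT sham libraries, whose other 6 read 4.97 to 15 FPKM. It read 9.86 to 10.9 in WT ADX+ADR, 12.7 to 15.4 in WT ADX+DEX and 5.93 to 27.1 in the 16 RE-RE libraries. Wdfy1 read 0.0574 to 0.622 in WT ADX, 1.81 to 4.11 in WT sham, 1.45 to 2.07 in WT ADX+ADR, 1.08 to 1.72 in WT ADX+DEX and 2.67 to 5.27 in RE-RE libraries. A difference of WT ADX from other conditions is thus not attributed to the adrenals alone.

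At ZT0, genes of energy metabolism were lower in WT ADX. The lipid droplet gene Plin3 fell from 14.4 ± 1.01 to 0.858 ± 0.58 FPKM (-4.45 ± 0.36, adjusted p = 1.65e-11), the triglyceride synthesis gene Dgat2 by 3.3 (-3.3 ± 0.36), the fast IIA myosin Myh2 (-2.87 ± 0.44) and glycogen branching enzyme Gbe1 (-1.51 ± 0.15). The insulin-responsive glucose transporter Slc2a4 (-0.69 ± 0.09), hexokinase Hk2 (-0.66), lipoprotein lipase Lpl (-0.73) and the coactivator Ppargc1a (-0.61) fell as well. All 20 oxidative phosphorylation genes fell, also adjusted over the list alone (adjusted p = 5.99e-14, and 0.374 with an estimated correlation). Of 9 mitochondrially encoded genes 8 fell (adjusted p = 1.69e-05, and 0.374 with an estimated correlation), of 18 fatty acid genes 13 fell (adjusted p = 3.06e-05, and 0.515 with an estimated correlation), and of 20 glucose genes 11 fell (adjusted p = 0.000417, and 0.269 with an estimated correlation). No member of these 4 lists rose. Of the mitochondrially encoded genes, mt-Co2, mt-Co3 and mt-Atp6 had means of 19.2, 17.7 and 16.7 FPKM over all libraries. The other members had 6391 to 20040, so the values of mt-Co2, mt-Co3 and mt-Atp6 are not read as transcript levels. Aldh1a1, which makes retinoic acid, was listed at 0 in all 3 WT ADX libraries and at 17.9 to 50.3 FPKM in WT sham, and Scd1, a fatty acid desaturase, at 0 against 3.09 to 9.13.

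Endothelial genes were higher at ZT0 in WT ADX. Pecam1 rose by 0.57 ± 0.1, Esam by 0.61 ± 0.09, Egfl7 by 0.65 and Cdh5 by 0.5, and 7 of 10 members rose with no fall (adjusted p = 0.000305, and 0.461 with an estimated correlation). Macrophage genes rose in 6 of 11 cases, 7 over the list alone (adjusted p = 0.00174, and 0.531 with an estimated correlation), and interferon response genes in 3 of 13 (adjusted p = 0.00683, and 0.732 with an estimated correlation). The interferon-induced Ifi27 (0.72) and the MHC genes H2-Q7 (2.23) and H2-Q6 (2.07) rose. Of the clock list 6 rose and 4 fell (adjusted p = 0.678, median -0.01, mean 0.19); Per3 rose by 0.96 ± 0.16, and Nfil3 (-1.85 ± 0.35) fell. Receptor targets at ZT0 had no common direction, with 1 up, 5 down and 19 not past (adjusted p = 0.703). Klf9 fell (-0.55 ± 0.1), while Sult1a1 rose by 0.58 ± 0.12. In all, 3838 genes were called, 1516 up and 2322 down, and 2130 with only these groups in the model.

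At ZT12, when the sham receptor targets were high, they fell with ADX. Klf15 fell from 20.1 ± 2.79 to 7.35 ± 0.0386 FPKM (-1.44 ± 0.14, adjusted p = 3.27e-09), and the atrophy factors Foxo1 (-0.91 ± 0.17) and Fbxo31 (-0.96 ± 0.09) fell. The target Cebpd, a CCAAT-binding factor, was listed at 0 in all 4 WT ADX libraries and at 5.61 to 26.5 in WT sham, and Ddit4 at 0 against 7.78 to 26.9. Of 25 targets 19 fell, 20 over the list alone, none rose, and 11 had a value at 0 (adjusted p = 1.91e-15, and 0.0478 with an estimated correlation). Oxidative phosphorylation genes fell in 18 of 20 cases, 19 over the list alone (adjusted p = 4.8e-09, and 0.498 with an estimated correlation). Fatty acid genes fell in 13 of 18 cases with 1 rise (adjusted p = 4e-04, and 0.596 with an estimated correlation), and glucose genes in 12 of 20 with 2 rises (adjusted p = 0.00154, and 0.325 with an estimated correlation). Muscle atrophy genes fell in 7 of 19 cases, 8 over the list alone (adjusted p = 0.00119, and 0.374 with an estimated correlation). Endothelial genes rose in 8 of 10 cases (adjusted p = 9.28e-07, and 0.289 with an estimated correlation), among them Kdr (0.8 ± 0.13) and Cdh5 (0.67). Usp2 (-1.13 ± 0.16), Tcap (-0.51) and Rora (-0.3) fell, and the immediate early gene Ier2 (1.57 ± 0.25) and Bcl6b (1.85 ± 0.24) rose. Immediate stress genes rose in 4 of 10 cases (adjusted p = 0.00403, 0.487 with an estimated correlation, and 0.0525 without genes listed at 0). Called genes numbered 3232, 1240 up and 1992 down, and 1828 with age as a covariate. Low genes depended on the offset: the fatty acid regulator Ppara fell by 1.79, or by 1.06 on log2(FPKM + 1).

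In WT ADX+ADR the time comparison asked what daily adrenaline adds. Targets of cAMP and adrenergic signalling rose at ZT12, the time of injection. The nuclear receptors Nr4a1 (54.6 ± 16.3 to 245 ± 30.5 FPKM; 2.2 ± 0.31, adjusted p = 2.68e-06) and Nr4a2 (2.14 ± 0.109 to 28.4 ± 2.37) rose. The kinase Sik1 rose by 3.11 ± 0.56. Outside the cAMP list, the insulin receptor substrate Irs2 rose by 1.77 ± 0.24, the mitochondrial carrier Slc25a25 by 3.18 ± 0.54 and Gadd45b, a growth-arrest gene of the immediate stress list, by 2.48 ± 0.24. In WT ADX+DEX, also injected at ZT12 but without adrenaline, Nr4a1 (2.11 ± 0.31), Slc25a25 (4 ± 0.54) and Gadd45b (1.78 ± 0.24) rose as well, so their rise is not particular to adrenaline. Irs2 there did not pass (0.44 ± 0.24, adjusted p = 0.186), and Nr4a2 was listed at 0 in all 8 libraries. Sik1 was listed at 0 in all 4 WT ADX+DEX libraries at ZT0 and at 2.51 to 4.71 FPKM at ZT12, against 27.9 to 35.3 with adrenaline. The time effects of the injected conditions were not tested against each other. Of the 18 members of the cAMP list 8 rose, 10 over the list alone, with no fall and no value at 0 (adjusted p = 3.84e-05, and 0.269 with an estimated correlation). With 5 shared members, the immediate stress list rose in 2 of 10 cases, 3 over the list alone (adjusted p = 0.0381, and 0.622 with an estimated correlation). Core clock genes rose in 11 of 19 cases and 3 fell, or 12 and 4 over the list alone (adjusted p = 3.56e-05, and 0.228 with an estimated correlation), led by Per3 (2.27 ± 0.14, adjusted p = 6.63e-14) and Nr1d2 (1.03 ± 0.09). Rhythmic output genes rose in 6 of 14 cases (adjusted p = 3.06e-05, and 0.0566 with an estimated correlation). Receptor targets rose in 7 of 25 cases, 8 over the list alone, with none falling (adjusted p = 0.0687), among them Tsc22d3 (0.6 ± 0.13) and Klf9 (0.39 ± 0.09). The sterol genes Srebf2 (-0.94 ± 0.08) and Insig1 (-0.5) and the chaperone Hsp90aa1 (-0.74) fell. Cholesterol synthesis had 4 falls and 1 rise among 7 (adjusted p = 0.00285, and 0.374 with an estimated correlation), and fibroblast and matrix genes 4 falls among 16, 7 over the list alone (adjusted p = 3.06e-05, and 0.531 with an estimated correlation). Called genes numbered 1527, 753 up and 774 down.

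Genes of the cAMP list were among those that passed the test of the difference from WT ADX. The time effect was larger with adrenaline for its members Nr4a2 (5.45 ± 1.22, adjusted p = 0.00575), Sik1 (3.72 ± 0.83) and Nr4a1 (1.87 ± 0.46, adjusted p = 0.0127), and outside it for Slc25a25 (3.16) and the stress list's Gadd45b (1.95 ± 0.35). The clock output repressor Bhlhe40 (1.26 ± 0.2, adjusted p = 9.93e-05), Nr1d2 (0.72 ± 0.14) and Nfkbia (1.12 ± 0.25) also had higher time effects. Nr4a1 (1.78 ± 0.46), Slc25a25 (3.97 ± 0.8) and Gadd45b (1.25 ± 0.35) passed the same test in WT ADX+DEX. Of the cAMP list 5 of 18 members were higher, 8 over the list alone, and none lower (adjusted p = 1.88e-05, and 0.237 with an estimated correlation). Of the immediate stress list 2 of 10 were higher, 4 over the list alone (adjusted p = 0.0264, and 0.605 with an estimated correlation). Of the clock list 3 were higher and none lower (adjusted p = 0.00365, and 0.415 with an estimated correlation). Of the receptor targets 2 were higher and 23 not past (adjusted p = 0.358, median -0.13, mean 0.83). The difference was called for 554 genes, 240 up and 314 down. The count was 340 without WT ADX+ADR ZT0 replicate 3, 338 without the 7 libraries that stood apart and 366 with only these groups in the model.

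Levels in WT ADX+ADR were compared with WT ADX at each time. WT ADX also differed from RE-RE ADX, which had no injections but another genotype. Over both times that contrast, added after the data were seen, called 6626 of 12000 genes. Against WT ADX, WT ADX+ADR gave 7856 and WT ADX+DEX 9251. Differences from WT ADX are thus not attributed to the hormones alone. At ZT0 some metabolic genes low in WT ADX were higher with adrenaline, which their choice on these libraries favours. Plin3 stood at 18.4 ± 1.09 against 0.858 ± 0.58 FPKM (4.8 ± 0.36, adjusted p = 4.7e-13), Fbxo31 was higher by 1.44 ± 0.1, Gbe1 by 0.99 and Slc2a4 by 0.74. Oxidative phosphorylation genes were higher in 16 of 20 cases (adjusted p = 8.21e-05, and 0.667 with an estimated correlation) and all 9 mitochondrially encoded genes were (adjusted p = 0.000155, and 0.461 with an estimated correlation). The latter include the low mt-Co2, mt-Co3 and mt-Atp6. Receptor targets were higher in 23 of 25 cases and lower in 2, with 12 listed at 0 somewhere (adjusted p = 7.57e-07, and 0.311 with an estimated correlation), among them Klf15 (1.72 ± 0.16). Endothelial genes were lower in 7 of 10 cases (adjusted p = 0.00233, and 0.531 with an estimated correlation), as in Cdh5 (-0.83), and Per3 (-1.77 ± 0.16) and Nr1d2 (-0.77 ± 0.1) were lower. H19, an imprinted RNA, read 1770 to 2150 FPKM in WT ADX and 0, 174, 0 and 0 with adrenaline, and its neighbour Igf2 11.6 to 12.5 and 0, 0, 0.669 and 0. As given above, 21 abundant genes were listed at 0 in WT sham and WT ADX alone, and 9 in the treated groups alone. Called genes numbered 6134, 3220 up and 2914 down.

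Genes of the cAMP list were among those higher in the same contrast at ZT12. Nr4a2 was higher by 5.39 ± 0.83, Nr4a1 by 1.94 ± 0.31 (adjusted p = 3.35e-06), and Sik1 by 2.98 ± 0.56. Gadd45b, of the immediate stress list and not of the cAMP list, was higher by 1.82. In the cAMP list 12 of 18 members were higher, 15 over the list alone (adjusted p = 0.000955, 0.374 with an estimated correlation, and 0.0563 without genes listed at 0, 5 of its members). Immediate stress genes were higher in 8 of 10 cases, 9 over the list alone (adjusted p = 0.0099, 0.531 with an estimated correlation, and 0.0617 without genes listed at 0). Handling is thus not excluded for the members these lists share. Receptor targets were higher in 24 of 25 cases (adjusted p = 4.83e-10, and 0.194 with an estimated correlation), and Klf15 by 1.66 ± 0.14. Oxidative phosphorylation was higher in 18 of 20 cases (adjusted p = 3.86e-05, and 0.64 with an estimated correlation), and all 9 mitochondrially encoded genes were (adjusted p = 0.000208, and 0.475 with an estimated correlation). The same low mt-Co2, mt-Co3 and mt-Atp6 are among these 9. The endothelial Cdh5 (-0.91) and Pecam1 (-0.65), the glucocorticoid receptor gene Nr3c1 (-0.54) and the calcium store gene Casq1 (-0.54) were lower. Called genes numbered 6357, 3326 up and 3031 down.

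Set against WT sham over both times, WT ADX+ADR had more immediate early and cAMP-responsive transcripts. Jun was higher by 2.7 ± 0.26, Ier2 by 1.76 ± 0.18, Apold1 by 3.01 ± 0.46 and the ubiquitin ligase Fbxo32 by 1.15. The immediate stress list, the sign of handling and RNA quality, was higher in 9 of 10 cases (adjusted p = 0.000208, and 0.368 with an estimated correlation), and macrophage genes in 9 of 11 (adjusted p = 0.00403, and 0.571 with an estimated correlation). The cAMP list was higher in 13 of 18 cases and lower in 1 (adjusted p = 0.000494, 0.374 with an estimated correlation, and 0.14 without genes listed at 0). Per3 (-0.7 ± 0.1), Lpl (-0.52) and Nr3c1 (-0.26) were lower. Receptor targets were higher in 18 of 25 cases and lower in 2 (adjusted p = 0.000208, 0.469 with an estimated correlation, and 0.0616 without the 12 listed at 0). Called genes numbered 6539, 3009 up and 3530 down. Uninjected RE-RE sham, described below, was also higher than WT sham for Jun and most of the immediate stress list. The 21 abundant genes listed at 0 in WT sham and WT ADX libraries alone include the immediate early gene Fos, at 0 in 5 of 8 WT sham libraries. Differences from WT sham are thus not attributed to ADX or adrenaline alone.

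In WT ADX+DEX the time comparison asked how a daily glucocorticoid dose shapes the difference. Nr1d1 rose from 20.9 ± 0.357 to 61 ± 3.23 FPKM (1.55 ± 0.17, adjusted p = 1.04e-08), and Nr1d2, its paralog among the clock repressors, rose by 1.64 ± 0.09. Per3 was listed at 0 in all 4 ZT0 libraries and at 5.85 to 6.43 at ZT12, and the repressor Cry1 fell by 1.07 (-1.07 ± 0.1). Core clock genes rose in 10 of 19 cases and fell in 5 (adjusted p = 0.00182, and 0.374 with an estimated correlation). Receptor targets went both ways, with 4 up, 7 down and 14 not past (adjusted p = 0.714): Nfkbia (1.91 ± 0.17, adjusted p = 3.12e-11) and Tsc22d3 (0.62 ± 0.13) rose, while Foxo1 (-1.14 ± 0.17) and Foxo3 (-0.57 ± 0.08) fell. Pfkfb3 rose by 2.95 ± 0.35, Slc25a25 by 4 ± 0.54, Nr4a1 by 2.11 ± 0.31 and the mineralocorticoid receptor gene Nr3c2 by 0.84 ± 0.11. The myogenic factor Myod1 (-1.25 ± 0.2), the vascular gene Egfl7 (-1.28 ± 0.12) and Hsp90aa1 (-0.88) fell. Heat shock genes fell in 5 of 13 cases with 1 rise (adjusted p = 0.025, and 0.51 with an estimated correlation). Amino acid and stress response genes fell in 4 of 6 cases with 1 rise (adjusted p = 0.0465, 0.374 with an estimated correlation, 0.131 with only these groups in the model, with a median of -0.45 and a mean of 0.15). Called genes numbered 3337, 1759 up and 1578 down.

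The difference from the WT ADX time effect was called for 2068 genes, 930 up and 1138 down. Nr1d1 (2.17 ± 0.26, adjusted p = 1.49e-07), Nfkbia (2.4 ± 0.25, adjusted p = 6.47e-09) and Pfkfb3 (3.26 ± 0.51) had larger rises with dexamethasone. Tacc2 (-2.79 ± 0.26), Dgat2 (-2.99), Glul (-1.83 ± 0.3, adjusted p = 4.55e-05), Foxo3 (-0.95 ± 0.12), Tcap (-0.86) and Slc2a4 (-0.66) had lower time effects. Oxidative phosphorylation genes were lower in 7 of 20 cases, 10 over the list alone (adjusted p = 0.000121, and 0.673 with an estimated correlation), and fibroblast and matrix genes higher in 6 of 16 (adjusted p = 0.000208, and 0.595 with an estimated correlation). Receptor targets had 3 higher, 4 lower and 18 not past (adjusted p = 0.562). With only these groups in the model 1347 genes were called.

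Against WT ADX at ZT0, targets of the glucocorticoid receptor were higher with dexamethasone. Glul stood at 165 ± 27.1 against 18.4 ± 2.69 FPKM (3.16 ± 0.22, adjusted p = 4.5e-15), the cell cycle inhibitor Cdkn1a at 92.6 ± 3.66 against 3.47 ± 2.69, Klf9 at 68.5 ± 7.16 against 26.5 ± 2.73, and Klf15 at 26.9 ± 3.4 against 5.56 ± 1.59. Fkbp5, a receptor co-chaperone, was listed at 0 in all 3 WT ADX libraries and read 80.6 to 98.9 with dexamethasone. Of 25 targets 23 were higher and none lower, with 11 listed at 0 somewhere (adjusted p = 1.01e-07, and 0.269 with an estimated correlation). The lipid droplet genes Plin3, at 52.1 ± 3.88 FPKM (6.3 ± 0.36), and Plin4 (4.83 ± 0.48) were higher, and fatty acid genes were higher in 16 of 18 cases and lower in 2 (adjusted p = 0.000247, and 0.571 with an estimated correlation). Atrophy genes were higher in 10 of 19 cases and lower in 3 (adjusted p = 0.0226, and 0.532 with an estimated correlation), with Map1lc3a at 2.29 ± 0.11, Foxo3 at 1.4 ± 0.09 and Eif4ebp1 at 1.68.

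Interferon response, vascular and matrix genes were lower with dexamethasone at ZT0. All 13 interferon response genes were lower (adjusted p = 0.000507, and 0.613 with an estimated correlation), such as the antiviral tetherin gene Bst2 (-2.72), and all 10 endothelial genes were (adjusted p = 0.000151, and 0.425 with an estimated correlation). Fibroblast and matrix genes were lower in 12 of 16 cases and higher in 1 (adjusted p = 0.000429, 0.613 with an estimated correlation, and 0.22 without the 9 members listed at 0). The collagen Col6a1 was lower (-3.64 ± 0.27), and Col3a1 was listed at 0 in all 4 libraries against 46.6 to 100 FPKM in WT ADX. Carbonic anhydrase Car3, abundant in slow fibres and fat, stood at 47.4 ± 32.4 FPKM against 2300 ± 311 (-5.97 ± 0.61), Casq1 was lower (-1.37), and the receptor's own gene Nr3c1 was lower (-0.89 ± 0.11). Called genes numbered 8265, 4365 up and 3900 down.

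At ZT12 all 25 targets were higher with dexamethasone than in WT ADX, 11 of them listed at 0 somewhere (adjusted p = 8.95e-10, and 0.194 with an estimated correlation). Nfkbia stood at 62.4 ± 3 against 10.3 ± 1.04 FPKM (2.61 ± 0.17, adjusted p = 8.56e-16), Errfi1, a brake on EGF receptor signalling, was higher by 3 ± 0.24 and Klf15 by 1.96 ± 0.14. Pnmt, which makes adrenaline from noradrenaline, stood at 39.9 ± 4.33 FPKM against 0.141 ± 0.148. Atrophy genes were higher in 14 of 19 cases and lower in 2 (adjusted p = 0.000913, and 0.374 with an estimated correlation), with Fbxo32 at 1.93, and clock genes in 10 of 19 with 1 lower (adjusted p = 0.0152, and 0.519 with an estimated correlation), with Nr1d1 at 1.81 ± 0.17. Endothelial genes were lower in 9 of 10 cases (adjusted p = 0.000153, and 0.425 with an estimated correlation) and interferon genes in 12 of 13 (adjusted p = 0.00415, and 0.692 with an estimated correlation). All 5 erythrocyte genes were lower, among them Hbb-bt (-1.43) and Alas2 (-1.43), without a call for the list (adjusted p = 0.179). Car3 (-4.87 ± 0.57), Sparc (-4.13) and Plxnd1 (-3.92) were lower. Called genes numbered 7957, 4150 up and 3807 down.

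Over both times WT ADX+DEX also differed from WT sham, with 8348 genes called, 4120 up and 4228 down. All 25 receptor targets were higher (adjusted p = 8.78e-09, and 0.235 with an estimated correlation), with Cdkn1a at 3.49 ± 0.3. Gnmt (5.07 ± 0.64), Lrg1 (3.48) and Errfi1 (1.99) were higher, and Car3 (-4.66 ± 0.4, adjusted p = 1.13e-12), Marcks (-3.07) and Nr3c2 (-0.68) lower. Interferon genes were lower in 11 of 13 cases (adjusted p = 0.0106, and 0.763 with an estimated correlation) and endothelial genes in 9 of 10 (adjusted p = 0.00308, and 0.532 with an estimated correlation). The limit given for WT ADX+ADR against WT sham holds here too, so these differences are not attributed to ADX or dexamethasone alone.

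In RE-RE sham the time comparison asked which daily differences a muscle shows when only brain and muscle hold Bmal1. The clock and receptor targets rose again. Per2 went from 1.35 ± 0.41 to 4.39 ± 0.724 FPKM (1.74 ± 0.27, adjusted p = 1.65e-05), Cry2 rose by 0.95 ± 0.09, Nr1d2 by 0.91 ± 0.09, and Clock fell (-1.07 ± 0.09, adjusted p = 1.59e-10). Sult1a1 rose from 6.42 ± 1.08 to 16.7 ± 0.891 (1.4 ± 0.12, adjusted p = 7.55e-11), Klf9 by 0.71 ± 0.09 and the kinase Sgk1 by 1.39 ± 0.21. Of 25 targets 16 rose, 20 over the list alone, none fell, and 8 had a value at 0 (adjusted p = 1.91e-15, and 0.0478 with an estimated correlation). Clock genes rose in 9 of 19 cases and fell in 5, or 10 and 5 over the list alone (adjusted p = 0.0351, 0.579 with an estimated correlation, and 0.0544 without genes listed at 0). Tcap rose from 1390 ± 30.5 to 3250 ± 102 FPKM, Usp2 by 1.7 ± 0.16, Adh1 by 2.15 ± 0.23, the muscle kinase Mylk4 by 1.87 ± 0.14 and Dusp7 by 2.24 ± 0.23. Myod1 (-0.98 ± 0.2), Nfil3 (-1.56 ± 0.33), Ypel2 (-1.67 ± 0.15) and Irs1 (-0.93) fell. Muscle atrophy genes rose in 5 of 19 cases with 1 fall, or 10 and 2 over the list alone (adjusted p = 0.00504, and 0.454 with an estimated correlation). Called genes numbered 1291, 688 up and 603 down, and 474 with only these groups in the model and 744 without the 7 libraries that stood apart. Genes called in both sham genotypes, which share no libraries, numbered 417 up and 356 down, where independent lists would share 96 and 57, and 6 went opposite ways.

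The difference between the genotypes' time effects was called for 41 genes, 19 up and 22 down. Tspan4 differed most plainly: it rose from 2.55 ± 0.349 to 7.1 ± 0.41 FPKM in WT sham and stood at 3.44 ± 0.292 and 3.53 ± 0.27 in RE-RE sham (difference -1.44 ± 0.13, adjusted p = 2.64e-09). The rise of Per2 was smaller in RE-RE sham (-2.59 ± 0.38, or -1.31 on log2(FPKM + 1)), and the collagen Col5a3 went the other way (2.23 ± 0.32). Clock genes had a lower time effect in 3 of 19 cases and a higher in 1, or 6 and 1 over the list alone (adjusted p = 0.0099, 0.498 with an estimated correlation, and 0.0559 with only these groups in the model). The immediate stress list moved up with no member called in limma, 5 at an unadjusted p under 0.05 (adjusted p = 0.000727, 0.374 with an estimated correlation, and 0.132 without genes listed at 0). Receptor targets had 1 higher and 1 lower (adjusted p = 0.0326, 0.725 with an estimated correlation, and 0.336 without genes listed at 0). The cAMP list moved up with 1 member called, 5 over the list alone (adjusted p = 0.000431, 0.374 with an estimated correlation, and 0.2 without genes listed at 0). Other lists moved with no member called in limma. Slow fibre genes went up (adjusted p = 0.0243, 0.614 with an estimated correlation, and 0.204 without genes listed at 0), as did oxidative phosphorylation (adjusted p = 0.029, and 0.853 with an estimated correlation). Fast fibre genes went down (adjusted p = 0.0311, 0.725 with an estimated correlation, 0.0626 with only these groups in the model, and 0.0738 without the 7 libraries that stood apart), as did nerve genes (adjusted p = 0.0302, and 0.732 with an estimated correlation). The count was 25 without RE-RE sham ZT12 replicate 8, 159 without ZT0 replicate 3, 135 without ZT12 replicate 7 and 24 without genes listed at 0. The share of calls that were higher was 46.3%, and 59.2% with equal library medians.

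Over both times RE-RE sham differed from WT sham in matrix, tendon and other cell-type genes. Col3a1 was higher by 1.59 ± 0.26, Mmp2, a matrix protease, by 1.35 ± 0.24, Col6a1 by 1.12 ± 0.18 and the tendon factor Scx by 0.95. Fibroblast and matrix genes were higher in 13 of 16 cases and none lower (adjusted p = 1.48e-05, and 0.515 with an estimated correlation). All 5 tendon genes were higher (adjusted p = 0.000935, and 0.336 with an estimated correlation), and macrophage genes in 6 of 11 cases, 8 over the list alone (adjusted p = 0.00541, and 0.6 with an estimated correlation). Adipocyte genes were lower in 4 of 8 cases (adjusted p = 0.0277, 0.0729 with age as a covariate, and 0.86 without the 5 members listed at 0). Oxidative phosphorylation genes were lower in 8 of 20 (adjusted p = 0.0147, 0.841 with an estimated correlation, and 0.133 with age as a covariate). Receptor targets were higher in 14 of 25 cases with none lower (adjusted p = 0.000431, and 0.498 with an estimated correlation), with Cdkn1a higher by 1.67 ± 0.3. The immediate stress and RNA quality list was higher in 6 of 10 cases, 7 over the list alone (adjusted p = 0.00989, 0.531 with an estimated correlation, and 0.22 without genes listed at 0). Its member Jun (2 ± 0.26), the slow-fibre gene Casq2 (1.06) and the fatty acid binding gene Fabp3 (0.91) were higher, and the methyltransferase Inmt (-2.25 ± 0.38), Fmo2 (-1.78 ± 0.11) and Irs2 (-1.13 ± 0.17) lower. The muscle stress gene Ankrd1 and mt-Co3 were listed at 0 in all 8 WT sham libraries and read 19.4 to 49.5 and 10.4 to 59.9 FPKM in RE-RE sham. For mt-Co3, whose values lay far under those of most mitochondrially encoded genes, this is not read as a difference in expression. Clock genes were higher in 6 of 19 cases and lower in 2 (adjusted p = 0.0944). Called genes numbered 4433, 2133 up and 2300 down, and 2936 without the 7 libraries that stood apart.

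In RE-RE ADX the time comparison asked what local clocks keep up without adrenals. Clock genes led the few calls. Per3 rose from 3.01 ± 0.599 to 5.69 ± 0.291 FPKM (0.94 ± 0.14, adjusted p = 0.000362), Cry2 by 0.63 ± 0.09, Tef by 0.44 ± 0.08, Usp2 by 0.84 ± 0.16 and Tcap by 0.63 ± 0.1. Clock (-0.61 ± 0.09) and Nr1d1 (-0.96 ± 0.17) fell. In the clock list 5 of 19 rose and 2 fell, or 9 and 4 over the list alone (adjusted p = 0.0109, 0.498 with an estimated correlation, and 0.0755 with age as a covariate). No receptor target passed the gene test in limma, 6 had an unadjusted p under 0.05, all upward, and 2 rose over the list alone. Their list nonetheless stood up (adjusted p = 0.0106, 0.632 with an estimated correlation, and 0.0987 without the 7 libraries that stood apart). Sult1a1 changed by 0.43 ± 0.12 (adjusted p = 0.06), Glul by 0.7 ± 0.2 (adjusted p = 0.0922) and Klf9 by 0.26 ± 0.09 (adjusted p = 0.203). Rhythmic output genes rose in 2 of 14 cases, 5 over the list alone (adjusted p = 0.00041, and 0.194 with an estimated correlation). Called genes numbered 93, 71 up and 22 down. The count was 25 without ZT0 replicate 1, 57 without ZT0 replicate 4, 24 without ZT12 replicate 5 and 40 without ZT12 replicate 8. It was 1 with only these groups in the model and, in limma, 0 without the 7 libraries that stood apart, with 580 genes at an unadjusted p under 0.05, and the genes above were not called there.

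The direct test of whether ADX altered the time effect in RE-RE mice called 8 genes. Sult1a1 (-0.96 ± 0.16, adjusted p = 0.00257) and Mylk4 (-1.21 ± 0.2, adjusted p = 0.00257) had smaller rises after ADX, and Ypel2 (1.15 ± 0.21), Dyrk2 (1.02 ± 0.18), Gramd4 (0.72) and Rreb1 (0.66 ± 0.11) higher time effects. The other called genes were Arntl, which rests on 3 libraries at 0, and Snord42a, with 7 values at 0. Of the receptor targets 1 had a lower time effect, 10 over the list alone, none a higher, and 8 had a value at 0 (adjusted p = 9.67e-16, and 0.0478 with an estimated correlation). The cAMP list moved up with no member called (adjusted p = 0.00976, 0.525 with an estimated correlation, and 0.178 without genes listed at 0). Counts were 13 and 19 without sham ZT0 replicates 1 and 3, 15 and 13 without sham ZT12 replicates 5 and 7, and 17 and 16 without ADX ZT12 replicates 5 and 8. The count was 2 with only these groups in the model, in which Sult1a1 and the others given here missed the test, and 25 without the 7 libraries that stood apart.

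RE-RE ADX was compared with RE-RE sham at each time. At ZT0 Sult1a1 (0.73 ± 0.12, adjusted p = 0.000564), Dusp7 (0.98 ± 0.23), Mylk4 (0.73 ± 0.14) and the matrix signalling gene Ccn2 (2.15 ± 0.4) rose. Lpl (-0.64 ± 0.12) and the fatty acid oxidation gene Hadha (-0.31) fell. Receptor targets rose in 4 of 25 cases with none falling and 8 listed at 0 somewhere (adjusted p = 2.54e-05, and 0.374 with an estimated correlation). Fatty acid genes fell in 7 of 18 cases, 9 over the list alone (adjusted p = 9.58e-05, and 0.531 with an estimated correlation), and heat shock genes in 3 of 13, 5 over the list alone (adjusted p = 0.00457, and 0.374 with an estimated correlation). Cell-type lists moved up alongside: adipocyte genes with 2 of 8 called (adjusted p = 0.0202, 0.361 on log2(FPKM + 1), and 0.768 in the other direction without the 5 members listed at 0), fibroblast and matrix genes with 1 of 16 (adjusted p = 0.00683, and 0.733 with an estimated correlation) and macrophage genes with no member called in limma (adjusted p = 0.0176, and 0.662 with an estimated correlation). A shift in cell types is thus not excluded for the lipid genes. Called genes numbered 654, 187 up and 467 down. The count was 168 and 1022 without sham replicates 1 and 3, and 348, 304, 328 and 377 without ADX replicates 1, 2, 3 and 4. It was 4 with only these groups in the model, where the 6 genes named here were not called, and 70 without the 7 libraries that stood apart, where Ccn2, Lpl and Hadha were not.

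At ZT12 the mitophagy gene Bnip3 (-0.38 ± 0.06, adjusted p = 0.000564), Fnip1, a partner of folliculin (-0.77 ± 0.14), the ubiquitin ligase Rnf167 (-0.52 ± 0.08) and the clock activator Rora (-0.34 ± 0.08) fell in RE-RE ADX. Receptor targets fell in 1 of 25 cases, 5 over the list alone (adjusted p = 0.00154, and 0.531 with an estimated correlation), and atrophy genes in 2 of 19, 5 over the list alone (adjusted p = 0.00293, and 0.415 with an estimated correlation). Fatty acid genes fell in 2 of 18 cases, 6 over the list alone (adjusted p = 0.000663, 0.613 with an estimated correlation, and 0.115 with age as a covariate). Slow fibre genes fell in 2 of 11 cases, 3 over the list alone (adjusted p = 0.0128, 0.583 with an estimated correlation, and 0.454 without genes listed at 0). With no member called in limma, interferon genes moved up (adjusted p = 0.0455, 0.0502 without the expression filter, 0.0602 without genes listed at 0, and 0.104 without the 7 libraries that stood apart). Fibroblast and matrix genes did as well (adjusted p = 0.0381, 0.827 with an estimated correlation, 0.0688 without genes listed at 0, and 0.067 without the 7 libraries that stood apart). Called genes numbered 638, 212 up and 426 down, 33.2% of them up, or 21.8% with equal library medians. The count was 407, 317 and 326 without sham replicates 5, 6 and 8, and 326, 317 and 256 without ADX replicates 5, 6 and 7. It was 271 with only these groups in the model and 76 without the 7 libraries that stood apart.

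The last contrast asked whether ADX acted differently in RE-RE and WT muscle, over both times. Some metabolic genes lower after ADX in WT had a higher ADX effect in RE-RE mice, which their choice on the same WT libraries favours. The difference was 3.6 ± 0.34 for Plin3 (adjusted p = 1.05e-09), 1.06 for Gbe1 and 0.54 for Slc2a4, but 0.16 ± 0.12 for Lpl (adjusted p = 0.362). For Klf15 it was 1.08 ± 0.15 (adjusted p = 1.97e-06), for Fbxo31 0.82 ± 0.09 and for Usp2 0.62. Oxidative phosphorylation genes had a higher ADX effect in RE-RE in 19 of 20 cases and none a lower (adjusted p = 3.71e-12, and 0.398 with an estimated correlation). Glucose genes had 8 of 20 higher and 1 lower (adjusted p = 0.0097, and 0.425 with an estimated correlation), and fatty acid genes, with 4 of 18 higher and 1 lower, were not called as a list (adjusted p = 0.0889). Receptor targets had a higher one in 14 of 25 cases, 16 over the list alone, and none a lower, with 12 listed at 0 somewhere (adjusted p = 2.88e-07, and 0.289 with an estimated correlation). Endothelial genes had a lower one in 7 of 10 cases, 8 over the list alone (adjusted p = 0.000121, and 0.425 with an estimated correlation), such as Pecam1 (-0.48) and Esam (-0.49), and Per3 also (-0.57 ± 0.15). Clock genes had 2 higher, 3 lower and 14 not past (adjusted p = 0.98). The difference was called for 2695 genes, 1659 up and 1036 down, and for 1174 without the 7 libraries that stood apart. The genotypes shared 202 genes that fell with ADX at ZT0 and 129 at ZT12, where independent lists would share 90 and 71, while 25 and 12 went opposite ways.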

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

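The differences between conditions below were planned, while the tests of explanations and the counts over other splits of the libraries were written down after the results had been seen. Results are listed here because 1 library lay far from the other 3 of its group or because an effect differed between groups.

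In 110 tests, of 10 measures in each of the 11 groups of 4 libraries, 8 found a library far from its group, where chance gives about 1 in 20. The number of genes listed at 0 was 362 in WT sham ZT0 replicate 1 against 219 to 234 in the others. It was 382 in WT ADX+DEX ZT12 replicate 8 against 278 to 284. Arntl read 0.327 FPKM in RE-RE sham ZT12 replicate 5 and 0 in the others. Per3 read 4.37 in WT ADX+ADR ZT12 replicate 7 against 5.89 to 6.11, and Nr1d1 20.3 in WT ADX+DEX ZT0 replicate 3 against 21 to 21.1. Klf9 read 44 in WT ADX+ADR ZT0 replicate 2 against 36.1 to 37.3. In RE-RE ADX ZT0 replicate 1, Glul read 29.3 against 54.6 to 58.8 and Sult1a1 9.48 against 10.8 to 11.

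The ADX effect over both times differed between WT and RE-RE mice in 2695 genes. With age as a covariate 2178 genes were called, but in RE-RE ADX the libraries apart were the youngest, so age is undecided. A larger spread between RE-RE libraries would raise their changes, yet the median absolute change at ZT12 in RE-RE was 0.723 of that in WT over 11050 genes never at 0, and the SDs had a ratio of 0.979. Without the 7 libraries that stood apart 1174 genes were called. With 6 groups then smaller, the parts of these libraries and of the genotype cannot be told apart. How much of the weaker ADX effect in RE-RE muscle belongs to genotype, age or genetic background stays open.

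Many abundant genes were listed at 0 in some libraries and expressed in others, 96 genes with a mean over 10 FPKM. In only 31.8% of the 255 pairs of gene and group with a 0 were all libraries of the group at 0, which argues against genes switched off in whole groups as the general cause. An adjustment of values between libraries before deposit is a candidate explanation: in genes listed at 0 in 1 to 9 libraries at most 13.0% of values came out as whole reads, against a chance of 10%, while genes mostly at 0 gave 97.3% with each value left out of the fit of its depth. With any length from 0.25 to 4 times the annotated one chosen for each gene, 2 of 492 of the former reached 90% whole reads, against 36 of 36 of the latter. The depths were fitted on genes mostly at 0, so their 36 of 36 is no independent result. With a depth fitted per library to as many low values of the former, the median share was 36.4% and the highest 55.6%. Which adjustment was made, and which of these genes were expressed in the libraries listed at 0, stays open.

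Glucocorticoid receptor targets were higher in WT ADX+ADR than in WT ADX, by a median of 1.2 (log2) over the 13 targets never at 0. An offset between WT ADX and the other libraries is a candidate explanation, since RE-RE ADX, also without adrenals and injections, exceeded WT ADX by a median of 0.58, with 13 of 13 higher and quartiles of 0.46 to 1.32. Against RE-RE ADX, WT ADX+ADR differed by a median of 0.07 (quartiles 0 to 0.2, 10 of 13 higher). Here the injections and the genotype cannot be told apart, because RE-RE mice had no injected group. An effect of adrenaline on these targets stays open, as does an effect of the genotype.

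Other splits of the same libraries were counted to see how often as many genes are called. With 35 splits, 1 of 35 is the smallest share possible, and no correction was made over the contrasts. Such counts also cannot tell time or treatment from a difference in how the libraries of a group were processed. In the time comparisons the real split was the 1 of 35 with the most genes. The counts were 2818 in WT sham (highest other 244), 1322 in WT ADX (413), 1527 in WT ADX+ADR (79), 3337 in WT ADX+DEX (357), 1291 in RE-RE sham (190) and 93 in RE-RE ADX (13). For RE-RE ADX the count was 1 with only its own groups in the model and 0 without the 7 libraries that stood apart. The real split also had the most genes, at 1 of 35, for WT ADX against sham at ZT0 (3838, highest other 2479) and ZT12 (3232, 382), and for RE-RE ADX against sham (654, 14, and 638, 9). The same held for WT ADX+ADR against WT ADX (6134, 4170, and 6357, 2124) and WT ADX+DEX against WT ADX (8265, 7002, and 7957, 3167). At 1 of 100 splits the real split had the most genes for WT ADX+ADR against WT sham (6539, 5025), WT ADX+DEX against WT sham (8348, 7022), RE-RE sham against WT sham (4433, 825) and the ADX effect between genotypes (2695, 1492).

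For the 5 differences in the time effect, chance was not excluded by these counts. At least as many genes came from 8 of 100 splits for WT ADX minus sham (185, highest other 2841), 10 of 100 for WT ADX+ADR minus WT ADX (554, 5061), 14 of 100 for WT ADX+DEX minus WT ADX (2068, 8052) and 10 of 100 for RE-RE sham minus WT sham (41, 761). For RE-RE ADX minus sham it was 3 of 100 (8, highest other 236), under the threshold set for chance. That share rests on 8 genes and on splits with the limit given next, so it is not read as excluding chance. Splits with several times the real count point to a structure of the samples. When libraries change condition unevenly between the 2 times, the large difference between the conditions enters the difference of the time effects. Among splits that exchanged conditions about evenly at both times, the highest counts were 73 among 42 splits for WT ADX minus sham, 3 among 39 for RE-RE ADX minus sham, 1 among 40 for WT ADX+ADR minus WT ADX, 147 among 53 for WT ADX+DEX minus WT ADX and 4 among 34 for RE-RE sham minus WT sham. Each lies under the real count.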

How the results depend on the processing

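The settings without genes listed at 0 and without the 7 libraries that share no exact values with their group were chosen after the data had been seen, and the other settings were planned. Depth could not be varied, since counts were not used here; at a median of 22.7 M reads it limits the genes near 0, whose changes depend on the offset. Of 1689 results for named genes, 1674 kept direction and call with equal medians, 1680 without the filter on low values, 1603 on log2(FPKM + 1), 1595 with age, 1518 without the 7 libraries and 1366 with only the groups compared in the model. A call was lost in 4, 9, 51, 85, 161 and 296 of them and gained in 11, 0, 34, 9, 10 and 27. Of 172 list calls 169, 167, 162, 163, 163 and 152 did so, and 4 did with an estimated correlation. Counts of called genes that moved over 1.5 times follow; apart from fewer libraries or genes where stated, the cause was not tested.

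Without the 7 libraries, a setting with fewer samples, the counts were 1295 for time in WT sham, 744 in RE-RE sham and 0 in RE-RE ADX (limma, 580 at an unadjusted p under 0.05). They were 70 and 76 for RE-RE ADX against sham at ZT0 and ZT12, and 2936 for RE-RE sham against WT sham. For differences in the time effect they were 96 for WT ADX minus sham, 25 for RE-RE ADX minus sham and 338 for WT ADX+ADR minus WT ADX, and 1174 for the ADX effect between genotypes. With only the groups compared in the model, which has fewer samples to estimate the spread, time gave 44 in WT ADX, 474 in RE-RE sham and 1 in RE-RE ADX. WT ADX against sham at ZT0 gave 2130, and RE-RE ADX against sham 4 and 271. The differences gave 70 for WT ADX minus sham, 2 for RE-RE ADX minus sham, 366 for WT ADX+ADR and 1347 for WT ADX+DEX minus WT ADX. With age as a covariate, RE-RE ADX time gave 53 and WT ADX against sham at ZT12 gave 1828. Without genes listed at 0, which has fewer genes, RE-RE sham minus WT sham gave 24, and of the named genes that could be compared 1126 kept their call, 2 lost and 7 gained one, while of list calls 130 held, 33 were lost and 2 reversed.

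The numbers of the replicates do not pair the samples: within WT ADX against sham at ZT0, 2 of 3 equal numbers correlated over 0.1 (-0.028 to 0.161), in WT ADX+DEX against WT ADX at ZT0 1 of 3, and in the other 6 comparisons 0. The replicate number as a block was fitted with only the groups compared in the model, so 2 settings change at once. With it, WT ADX against sham gave 7 at ZT0 and 280 at ZT12, and RE-RE ADX against sham 0 (limma, 2268 at an unadjusted p under 0.05) and 18. WT ADX+ADR against WT ADX gave 2682 and 1719. The differences in the time effect gave 4 for WT ADX minus sham, 0 for RE-RE ADX minus sham (limma, 831 at an unadjusted p under 0.05), 62 for WT ADX+ADR and 262 for WT ADX+DEX minus WT ADX, and 17 for RE-RE sham minus WT sham. Of named genes 897 kept their call with the block, 413 lost and 11 gained one, and of list calls 110 held and 17 were lost. Fewer libraries and the block terms leave fewer residual degrees of freedom than the 35 of the main model. The part of the block itself was not tested.

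Leaving out 1 library at a time, which leaves fewer samples, gave 547 to 1610 for time in WT ADX, 24 to 123 in RE-RE ADX, and 168 to 1022 and 256 to 765 for RE-RE ADX against sham at ZT0 and ZT12. For the differences in the time effect it gave 118 to 233 for WT ADX minus sham, 8 to 19 for RE-RE ADX minus sham, 340 to 626 for WT ADX+ADR minus WT ADX and 25 to 159 for RE-RE sham minus WT sham. The other 15 counts stayed within 1.5 times. Among named genes 18115 such results kept direction and call, 888 lost and 138 gained a call, and 0 reversed.

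Results that reversed were 3. Without genes listed at 0, the adipocyte list in RE-RE ADX against sham at ZT0 (adjusted p = 0.768) and the fibroblast and matrix list in WT ADX+DEX against WT ADX at ZT12 (adjusted p = 0.998) changed sides; these lists then hold fewer genes. On log2(FPKM + 1), the difference of Npas2 in WT ADX+DEX minus WT ADX was -0.04, and the cause was not tested.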

Other observations

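The genes and lists in this part were chosen after their values had been seen, and the lists themselves and their tests were fixed before.

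Nerve and Schwann cell genes went down after ADX in WT mice. At ZT0 4 of 8 fell, 6 over the list alone (adjusted p = 0.0421, 0.763 with an estimated correlation, and 0.056 to 0.133 under 6 alternatives), and at ZT12 5, 7 over the list alone (adjusted p = 0.0142, and 0.667 with an estimated correlation). The Schwann cell factor Sox10 fell by 1.86 (-1.86 ± 0.34, adjusted p = 7.77e-05) at ZT0. In WT ADX+ADR 7 members stood higher than in WT ADX at ZT0 (adjusted p = 0.00589, and 0.614 with an estimated correlation), with Sox10 at 2.45 ± 0.34. At ZT12 2 did (adjusted p = 0.653). In RE-RE ADX against sham 0 of 8 members passed the test in limma at either time.

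Fast fibre genes rose from ZT0 to ZT12 in WT sham, with 6 up and 1 down of 12 (adjusted p = 0.00504, and 0.608 with an estimated correlation). Slow fibre genes fell in 3 of 11 cases there (adjusted p = 0.0455, 0.667 with an estimated correlation, and 0.248 without genes listed at 0). In RE-RE ADX 1 slow fibre gene fell, 5 over the list alone (adjusted p = 0.000208, 0.374 with an estimated correlation, and 0.0526 without genes listed at 0). Satellite cell and denervation genes were not called as a list for WT ADX+DEX against WT sham, with 2 of 8 higher and 5 lower (adjusted p = 0.442). The neural cell adhesion gene Ncam1 was lower there (-1.41 ± 0.11, adjusted p = 2.67e-14). The 4 adrenal hormone receptor genes rose in 2 cases from ZT0 to ZT12 in WT ADX+DEX (adjusted p = 0.0311, 0.289 with an estimated correlation, and 0.0678 with only these groups in the model).

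Further cell-type lists were called with camera, those given here among them, and none held with an estimated correlation. From ZT0 to ZT12, tendon genes fell in WT ADX (2 of 5, all 5 over the list alone, adjusted p = 0.000431). Macrophage genes fell in WT ADX+ADR (2 of 11, adjusted p = 0.0226), WT ADX+DEX (5, adjusted p = 0.0131) and RE-RE ADX (none called in limma, adjusted p = 0.0455, 0.505 with age as a covariate, 0.135 without the 7 libraries that share no exact values with their group, and 0.0504 without the expression filter). Interferon genes rose in WT ADX+DEX (4 of 13, adjusted p = 0.0421, and 0.214 on log2(FPKM + 1)). In WT ADX against sham, fibroblast and matrix genes were higher at ZT0 (3 of 16, adjusted p = 0.011) and interferon genes at ZT12 (4 of 13, adjusted p = 0.00119). In WT ADX+ADR, tendon genes were higher than in WT ADX at ZT12 (4 of 5, adjusted p = 0.0103) and than in WT sham (all 5, adjusted p = 0.00654), and endothelial genes lower than in WT ADX at ZT12 (7 of 10, adjusted p = 0.00457, and 0.0555 with only these groups in the model). In WT ADX+DEX, fibroblast and matrix genes were lower than in WT ADX at ZT12 (10 of 16, adjusted p = 0.0381, 0.0809 on log2(FPKM + 1), and 0.998 in the other direction without genes listed at 0) and than in WT sham (11 of 16, adjusted p = 0.01, and 0.889 without genes listed at 0), and nerve genes higher than in WT ADX at ZT0 (6 of 8, adjusted p = 0.0341, and 0.0678 with only these groups in the model). The ADX effect on nerve genes was higher in RE-RE than in WT in 5 of 8 cases (adjusted p = 0.0062).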
